A study of Mus musculus with 6 samples.

How the data were processed

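Small RNA was sequenced from primary mouse pulmonary artery smooth muscle cells in 3 hypoxia libraries (3% oxygen, 24 hours) and 3 normoxia libraries. Per the labels, total RNA was treated with enzymes by the Pandora-seq strategy before library construction, and the submitters' processing notes name the mouse build mm10. The aligner, the annotation tool, the tRNA reference and any filter are not given in the sources used here. The deposited values are raw counts, not normalized, in a table of 38798 distinct sequences of 15 to 45 nt, with 0 repeated sequences. The table assigns each sequence to 1 or more tRNAs and to a class: 5' end, 3' end without CCA, CCA end, internal (all other mature fragments) or precursor. Fragments that end in the C or CC of an incomplete tail are in the internal class, not among the 3' ends without CCA. Sequences assigned to more than 1 family numbered 3114 and held 35.0% of all counts. Each was kept as 1 tsRNA and counted once for each family the table gives it. Groups and replicate numbers came from the sample titles, and the design text calls the replicates biological. In fits with the group alone the p-values rest on the spread between these 3 cultures per group. In fits that also model the replicate number they rest on the spread left after differences between replicate numbers are taken out.

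Mitochondrial tRNA genes were taken from GENCODE M21 and nuclear tRNA gene locations and lengths from RefSeq, both on GRCm38, the assembly of mm10. Mitochondrial positions were found by exact matching of each sequence to the tRNA gene followed by CCA. For mature tRNA-Asp-GTC the most abundant 5' and 3' fragments of at least 30 nt were taken first. The longest 5' and 3' fragments that extend them overlap by 17 nt and were joined. Of the family's counts 95.7% lie inside the joined sequence. Nuclear tRNAs were not mapped to single genes, since their copies share sequences.

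Tests across tsRNAs used edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, trimmed-mean scaling, filterByExpr by group, Benjamini-Hochberg adjusted p under 0.05), with the group as the only term. The filter kept 6452 tsRNAs with 96.3% of all counts and all 73 tRNA families. DESeq2 1.42.0 (Wald test) and limma 3.58.1 (voom) were the other tools. CPM scales counts to 1e+06 per library. For tested tsRNAs and families (scaled CPM) the total is corrected by the trimmed-mean factor, and CPM of all counts uses each library's plain total. Sequence ratios per pair add 0.5 CPM. Lists were tested with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry (directional and mixed), over 33 lists: each amino acid of nuclear tRNAs with suppressor and initiator tRNAs apart, mitochondrial tRNAs, the 5 fragment classes, the tRNAs Asp, Glu, Gly and Tyr together, the sources of abundant long 5' fragments (Gly-GCC, Glu-CTC, Lys-CTT, Val-CAC, Val-AAC, His-GTG), the sources of sex-hormone-dependent long fragments (Asp-GTC, His-GTG, Lys-CTT) and the DNMT2 substrates. The lists overlap, since an amino acid can be in several and the amino acid lists include precursor fragments. Shares and sums were compared by two-sided exact permutation tests in SciPy 1.17.1 (Python 3.11.15, pandas 2.3.3), and figures were drawn with matplotlib 3.10.9. Counts are of reads without molecular identifiers, so that counting error is a lower bound of the error.

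The tests, the lists, the rule for named tsRNAs and most alternatives were fixed before the data were examined. The rule took tsRNAs past the adjusted threshold and, where none passed, the 4 higher and 4 lower ones with the smallest unadjusted p. Its other conditions (a mean of at least 10 CPM, no overlap between groups, 1 tsRNA per family and class) were kept for these 8. It added the 5 most abundant tsRNAs and, for tRNA-Asp, the 3 most abundant, the 3 most abundant internal ones and the internal one with the smallest p. The 10 tsRNAs past the threshold with the replicate block, the families past it in other settings, the 2 tRNA-Asp fragments called by DESeq2, the precursor families, the mitochondrial tRNA-Val end positions and the tRNA-Asp start position were chosen after their values were seen.

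Whether the replicate numbers pair the samples was checked by correlating the deviations of same-numbered libraries from their group means, which gave 0.81, 0.53 and 0.45. Among replicates 2 and 3 alone the correlation was -0.03, so that the pairing rests on replicate 1 standing apart from the others in both groups. The common dispersion was 0.706 with the group alone, 0.213 with the replicate block and 0.228 with a term for replicate 1 against the others. The alternatives tried were other scalings (DESeq2 size factors, library size, upper quartile), no filter, a filter of at least 10 counts in 3 libraries, DESeq2, limma voom, the replicate block, each library left out, and sequences of several families left out. Chosen after seeing the data were the block combined with each other tool and scaling and with each pair left out, a batch term for replicate 1, replicates 2 and 3 alone, and precursors as families of their own.

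The fits were tested on simulated data in which each replicate number had its own mean, taken from the real libraries. Of 6452 tsRNAs 200 were changed. The filter then left 5754, and changed ones that it removed counted as not recovered. The spread was that of the blocked fit, so these data follow the blocked model. The gain with the block is therefore built in and is no evidence that the block suits the real data. With the group alone edgeR recovered 0 of 100 changed 2-fold and 0 of 100 changed 4-fold, and with the replicate block 7 and 34. Without a difference between replicate numbers it recovered 4 and 38 with either model. For 72 simulated families the group alone recovered 0 of 10 at 2-fold and 2 of 10 at 4-fold, and the block 10 of 10 at both. Camera found simulated lists moved 2-fold in the right direction with and without the block and with either correlation. Their members were drawn independently and all moved alike. The check therefore does not tell what camera finds in lists whose members are correlated or move less.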

Results

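Small RNA libraries were made from primary mouse pulmonary artery smooth muscle cells, the contractile cells of the lung's arterial wall, grown in normoxia or kept at 3% oxygen for 24 hours. Each group held 3 biological replicates. The libraries were made by Pandora-seq, in which enzymes first take off RNA modifications that block the cloning of small RNAs. The deposited counts covered 38798 distinct sequences of 15 to 45 nt assigned to tRNAs, called tRNA-derived small RNAs (tsRNAs). The hypoxia libraries held 510519, 2563749 and 1713960 tsRNA counts in replicates 1, 2 and 3, and the normoxia libraries held 330787, 2217965 and 1629726. The mean total was 1596076 ± 1031679 in hypoxia and 1392826 ± 965635 in normoxia (SD, n = 3 per group; two-sided exact permutation test, p = 0.7). Hypoxia libraries held 19134 ± 3148 distinct tsRNAs with at least 1 count and normoxia libraries 17336 ± 1653 (exact p = 0.4), and 6350 ± 1207 against 5630 ± 1617 with at least 10 counts (exact p = 0.6). For these exact tests of 3 against 3 the smallest p possible is 0.1. All values below are means ± SD over n = 3 libraries per group unless a standard error (SE) is named.

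Both libraries numbered 1 stood apart from the other 4. They held 36.6% and 34.6% of their counts in 5' end fragments, against 53.0% to 58.6% in the other libraries, and 15.3% and 14.4% in mitochondrial tRNA fragments, against 6.0% to 7.33%. Across tsRNAs, log2 normalised counts (CPM, counts scaled to the library total) correlated at r = 0.901 between hypoxia replicate 1 and normoxia replicate 1, and at 0.491 to 0.532 between either of them and a library numbered 2 or 3. The replicate number was therefore also used as a block, in a setting listed before the data were examined, and its values stand beside the results it changes. Among replicates 2 and 3 alone the deviations of hypoxia 2 and normoxia 2 did not correlate (r = -0.03). Pairs 2 and 3 are therefore matched by number only.

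Hypoxia-responsive tsRNAs were the stated aim of the comparison. In the 3' part of mitochondrial tRNA-Val, 5 overlapping fragments ending before its CCA tail were higher in hypoxia in all 3 same-numbered library pairs. Fragments of mitochondrial tRNA-Ser-GCT, mitochondrial tRNA-Ile-GAT, nuclear tRNA-Ile-TAT and a tRNA-Tyr-GTA precursor were lower in each pair. These differences passed the test only in fits that took account of the replicate number or left replicate 1 out. They were chosen by the fit with the replicate block. Agreement of the 3 pairs is favoured by that choice and is no separate support. Mitochondrial tRNAs are encoded in the mitochondrial genome and serve translation of the respiratory chain's subunits made there. In the comparison of the groups alone, edgeR called 0 of 6452 tested tsRNAs at an adjusted p of 0.05, with 18 higher and 27 lower at an unadjusted p under 0.05. DESeq2 called 0 (34 and 50 at unadjusted p) and limma voom 0 (56 and 53), and 0 passed with at least a 2-fold change in any of the 3 tools. With the replicate block, edgeR called 5 higher and 5 lower, all by at least 2-fold (220 and 192 at unadjusted p).

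The 5 tsRNAs that rose in the blocked fit were all from mitochondrial tRNA-Val-TAC, encoded by mt-Tv (mm10 chromosome M, 1025 to 1093). All lie within positions 48 to 69 of the tRNA and overlap, so they are not 5 separate signals. The most abundant, ATGACCAATGAACACTCT (positions 50 to 67 of the tRNA, chromosome M 1074 to 1091), averaged 7541 ± 8741 CPM in hypoxia and 2405 ± 2092 in normoxia, a blocked fold of 2.50 (log2 1.32, SE 0.26, adjusted p = 0.0184). Without hypoxia replicate 1, which leaves normoxia replicate 1 unmatched, its unblocked log2 change moved from 1.65 to 0.10, and without normoxia replicate 1 to 2.63. ACCAATGAACACTCTGA, which ends on the last encoded base of the tRNA, had 74.2 ± 63.1 against 8.53 ± 8.95 CPM, a blocked fold of 9.72 (log2 3.28, SE 0.56, adjusted p = 0.00641). Its counts were 92, 81 and 51 in hypoxia and only 8, 5 and 5 in normoxia. The other 3, TCATGACCAATGAACACTCT, TGACCAATGAACACTCT and ATGACCAATGAACACTC, had blocked log2 changes of 1.80, 1.63 and 2.06. Without hypoxia replicate 1 the unblocked changes of these 4 moved from 3.23, 2.14, 1.84 and 2.09 to 2.34, 1.24, 0.86 and 0.86. Without normoxia replicate 1 the first moved to 4.40 and the last to 3.29. Of the 5 that fell, AAGAAAGATTGCAAGAACTGCT, the 5' end of mitochondrial tRNA-Ser-GCT (mt-Ts2, chromosome M 11613 to 11634), had 256.6 ± 46.0 CPM in hypoxia and 1009 ± 379 in normoxia. Its log2 change was -1.93 in the blocked fit (SE 0.31, adjusted p = 0.00327) and -1.97 without the block (SE 0.53, adjusted p = 1.0). AATGCCGAGGTTGTGAGTTCGAGCCTC, an internal fragment of tRNA-Ile-TAT, had 99.2 ± 32.1 against 368.4 ± 176 CPM (blocked log2 -1.85, SE 0.36). The precursor fragment GCTTGTGGCTGTGGAC of tRNA-Tyr-GTA had 7.57 ± 6.57 against 67.2 ± 12.7 CPM (blocked log2 -3.17, SE 0.62), with 0 counts in hypoxia replicate 1. Both fragments of mitochondrial tRNA-Ile-GAT (mt-Ti), ATGTCTGATAAAAGAATTACTTTGAT and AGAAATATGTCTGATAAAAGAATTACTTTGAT, had 16.2 ± 22.2 and 15.9 ± 25 CPM in hypoxia and 85.8 ± 46.3 and 66.6 ± 49.3 in normoxia (blocked log2 -3.32 and -3.21). Most of the hypoxia mean came from replicate 1, with 41.6 and 44.8 CPM, and without that library the unblocked log2 changes moved from -2.45 to -4.60 and from -2.12 to -5.39, the second also to -1.40 without normoxia replicate 1. The first of these mitochondrial tRNA-Ile-GAT fragments lies inside the second, so they are not separate signals either. Of the 10 blocked calls 0 passed without pair 2, 7 without pair 1 and 10 without pair 3, all in the same direction. Without pair 2 the log2 changes were 1.46 to 3.09 for those that rose and -3.77 to -1.56 for those that fell, against 1.32 to 3.28 and -3.32 to -1.85 with all pairs. The SE were 0.41 to 0.92 against 0.26 to 0.65. With replicate 1 against replicates 2 and 3 as a batch term 5 of the 10 passed, and with replicates 2 and 3 alone 1 passed, the fragment of mitochondrial tRNA-Ser-GCT, and all 10 kept their direction in both.

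**Figure D1:**
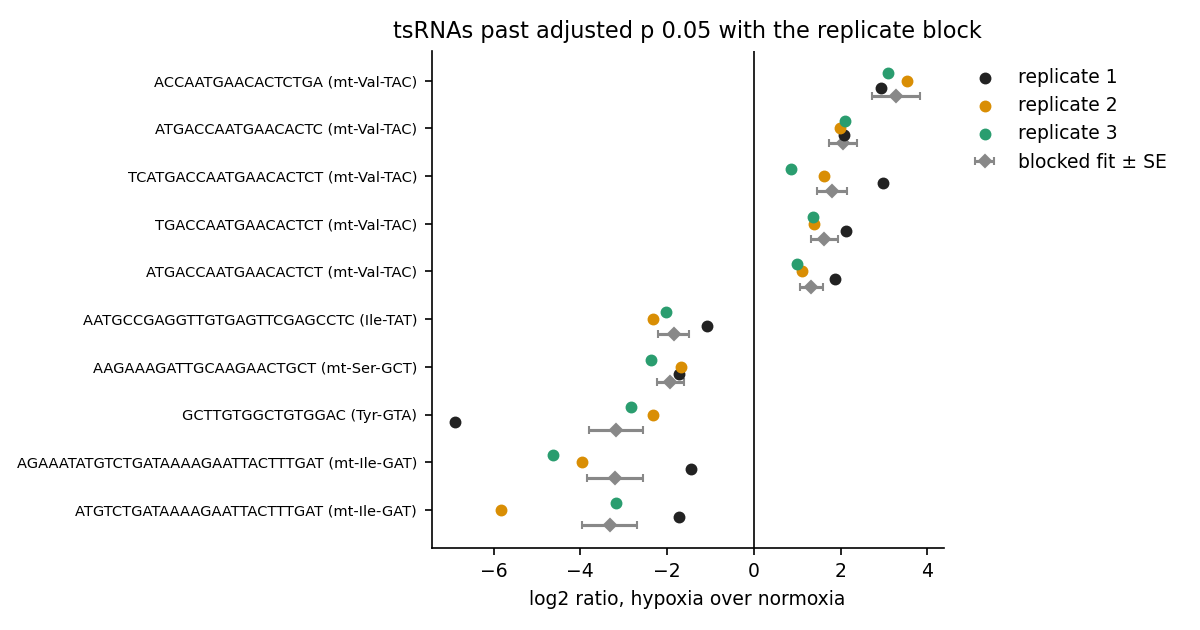
Log2 ratio of hypoxia over normoxia CPM (horizontal axis) in each same-numbered pair of libraries (coloured points) for the 10 tsRNAs past an adjusted p of 0.05 with the replicate block, with the blocked estimate ± SE (grey diamonds). All 3 pairs lie above 0 for the 5 mitochondrial tRNA-Val fragments and below 0 for the other 5. The tsRNAs were chosen by a fit with these pairs as blocks, which favours such agreement.

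By the rule fixed before the data were examined, 8 tsRNAs were named by the smallest unadjusted p, and none of them passed without the block. Those higher in hypoxia included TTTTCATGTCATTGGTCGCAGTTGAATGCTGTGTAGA of mitochondrial tRNA-Glu-TTC (mt-Te), with 53.9 ± 8.56 against 10 ± 3.06 CPM (log2 2.41, SE 0.64), and GAGAGGTCCCGGGTTC, shared by the 3 tRNA-Pro families, with 36.5 ± 18.8 against 9.07 ± 1.85 CPM (log2 2.01, SE 0.70, and 1.41 without hypoxia replicate 2). The other 2 were TCATGACCAATGAACACTCT and ACCAATGAACACTCTGA of mitochondrial tRNA-Val, given above. Those lower in hypoxia were the mitochondrial tRNA-Ser-GCT fragment given above, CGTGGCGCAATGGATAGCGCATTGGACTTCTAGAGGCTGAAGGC of a tRNA-Arg-TCT precursor (log2 -2.47, SE 0.72), ACTTTTAATCTGAGGG of tRNA-Lys-TTT (log2 -3.21, SE 0.96) and AATTAGTAGATTCTGAATAAAC of mitochondrial tRNA-Gly-TCC (log2 -3.10, SE 0.97, and -3.75 without hypoxia replicate 1). The 5 tsRNAs with the highest mean CPM did not pass either. GGGGATGTAGCTCAG, a 5' end shared by the tRNA-Ala families, took 54914 ± 43736 CPM in hypoxia and 78001 ± 66952 in normoxia (log2 -0.51, SE 1.29). Its 3 longer forms ending in GTG, GTGG and GTGGT had log2 changes of -0.61, -0.23 and -0.03, and AGGATTCGGCGCTCTC, internal to tRNA-Glu-CTC, had 0.42 (SE 0.84). Over all 6452 tested tsRNAs, 978 (15.2%) were higher in hypoxia in all 3 pairs and 847 (13.1%) were lower in all 3, where chance gives 12.5% each. The groups did not overlap for 321 (4.98%). The 10% of exchangeable libraries is no reference here, since both libraries numbered 1 stand apart.

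Mitochondrial tRNA-Val fragments that stop just short of the tRNA's encoded 3' end were higher in hypoxia in all 3 pairs. Those whose last base was at position 65, 66 or 67 of the 69 encoded had 37336 against 10055 CPM in pair 1, 5468 against 2226 in pair 2 and 3888 against 1850 in pair 3, folds of 3.71, 2.46 and 2.10 (exact p = 0.5 over the 3 libraries per group). Without hypoxia replicate 1, which leaves normoxia replicate 1 unmatched, the difference of the group means was -32.3 CPM. The CCA tail is added after transcription and is needed for charging with an amino acid. Fragments that carry it in full had 8635 ± 2124 CPM in hypoxia and 13605 ± 2875 in normoxia (exact p = 0.1). They were lower in all 3 pairs, by folds of 0.380, 0.686 and 0.960, so that pair 3 was nearly unchanged. Fragments ending at position 71, in the CC of the tail, were higher in all 3 pairs, by folds of 1.13, 1.25 and 1.78 (exact p = 0.2). Fragments with the full CCA made up 24.5 ± 11.5% of fragments ending at positions 64 to 72 in hypoxia and 46.9 ± 1.23% in normoxia, without overlap (exact p = 0.1). This set of end positions was chosen after the values were seen. No sequence in the data is shorter than 15 nt, so fragments with a late start are seen only when they reach into the tail. The share therefore mixes fragments of different start positions.

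**Figure D2:**
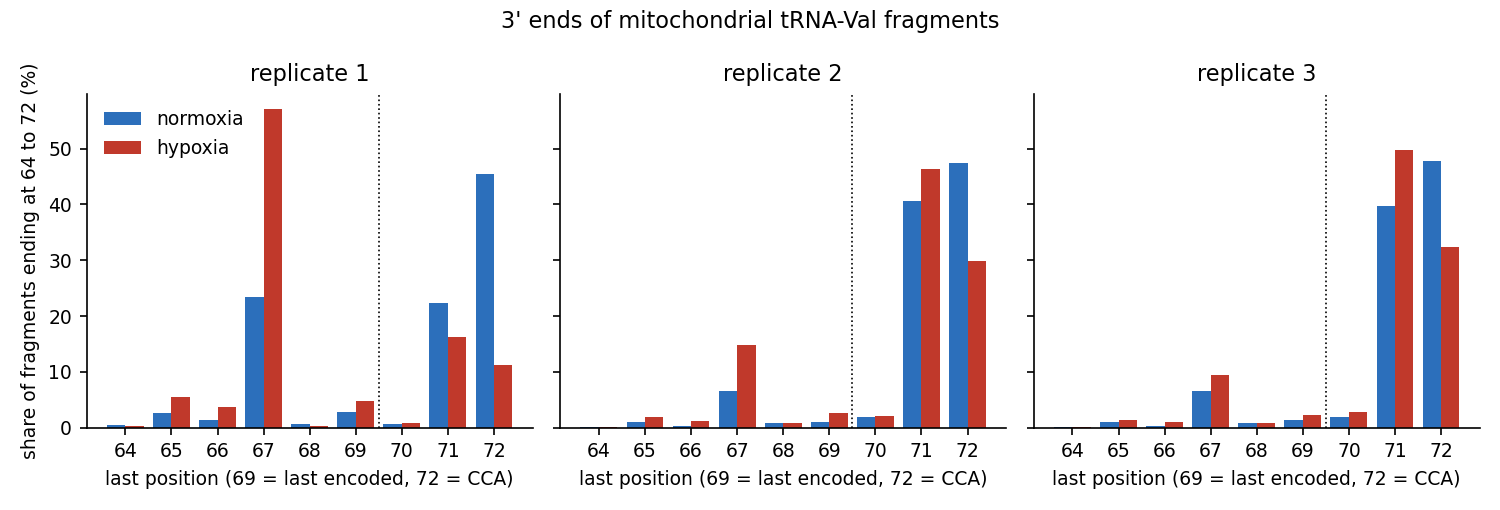
Share of mitochondrial tRNA-Val fragments (vertical axis, percent of those ending at positions 64 to 72) by last position (horizontal axis) in each library, hypoxia in red and normoxia in blue. Position 69 is the last encoded base (dotted line after it) and position 72 the last base of the CCA tail, where each hypoxia library (11.2% to 32.3%) lies below each normoxia library (45.5% to 47.8%).

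Summed by tRNA family, fragments of mitochondrial tRNA-Gly-TCC and mitochondrial tRNA-Phe-GAA were lower in hypoxia in all 3 pairs and fell in the blocked fit. Mitochondrial tRNA-Gly-TCC had 4595 ± 2543 scaled CPM in hypoxia and 7911 ± 3823 in normoxia (blocked log2 -0.81, SE 0.16, adjusted p = 0.0111), and mitochondrial tRNA-Phe-GAA had 31.7 ± 23 against 70.9 ± 25.1 (blocked log2 -1.31, SE 0.24, adjusted p = 0.00659). Their unblocked log2 changes of -0.78 and -1.17 ran from -1.34 to -0.33 and from -1.93 to -0.84 without each replicate in turn. A family annotated as suppressor tRNA with anticodon TTA also fell (blocked log2 -2.70, SE 0.28, adjusted p = 6.83e-05), on 1, 4 and 3 counts in hypoxia and 2, 27 and 19 in normoxia. Without the block, edgeR called 0 of 73 families (0 higher and 2 lower at unadjusted p), limma voom 0 (0 and 3 at unadjusted p), and DESeq2 called 2, the suppressor family and mitochondrial tRNA-Asp-GTC, both lower. The median family log2 change was -0.07 with trimmed-mean scaling and 0.11 with DESeq2 size factors, so that 26 families lay above 0 with the first and 50 with the second. Relative to that median the unblocked change of mitochondrial tRNA-Gly-TCC was -0.72 with the first and -0.71 with the second, and that of mitochondrial tRNA-Phe-GAA was -1.10 with both. With DESeq2 size factors in the blocked edgeR fit, 3 families rose (tRNA-Asp-GTC, tRNA-Leu-AAG and tRNA-Leu-TAG) and only the suppressor family fell. Both tRNA-Leu families had near-equal pair log2 ratios (0.217, 0.202 and 0.517 for AAG, 0.209, 0.205 and 0.524 for TAG). Shared sequences count in each family, so these may not be separate signals. In that fit mitochondrial tRNA-Gly-TCC was at -0.63 (SE 0.18, adjusted p = 0.0938) and mitochondrial tRNA-Phe-GAA at -1.14 (SE 0.30, adjusted p = 0.084). Relative to the median they were at -0.75 and -1.26 in both blocked fits, so that the scaling moved them with the other families. Without pair 2, 0 families passed in the blocked fit (these 2 at -0.88 and -1.31, SE 0.19 and 0.47), and with replicates 2 and 3 alone 8 fell, 7 of them mitochondrial.

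Fragments of precursor tRNAs, which still hold sequence that is removed during maturation, were lower in hypoxia in each pair. They came from 4 families, tRNA-Arg-TCT, tRNA-Ile-TAT, tRNA-Leu-CAA and tRNA-Tyr-GTA, whose mouse genes include ones with introns, and made up 0.0414 ± 0.0225% of counts in hypoxia and 0.141 ± 0.0333% in normoxia, without overlap (exact p = 0.1). Precursor fragments of tRNA-Arg-TCT had 250.3 ± 143 CPM of all counts in hypoxia and 839.7 ± 88.3 in normoxia, those of tRNA-Tyr-GTA 150.5 ± 81.1 and 518.8 ± 222, and those of tRNA-Ile-TAT 6.77 ± 2.66 and 36.1 ± 18.5. Those of tRNA-Leu-CAA were few, at 6.11 ± 5.03 and 13.9 ± 7.53 CPM. Mature fragments of the same 4 families had 40925 ± 11298 CPM in hypoxia and 41928 ± 8422 in normoxia (exact p = 0.8). Those of tRNA-Ile-TAT alone had 2770 ± 691 and 3847 ± 753 (exact p = 0.2), with pair folds of 1.04, 0.582 and 0.601. Tested as families of their own, a choice made after the values were seen, precursors of tRNA-Arg-TCT (log2 -1.78, SE 0.36, adjusted p = 0.00914), tRNA-Ile-TAT (-2.02, SE 0.48, adjusted p = 0.0174) and tRNA-Tyr-GTA (-1.66, SE 0.43, adjusted p = 0.0174) fell in the blocked edgeR fit, each lower in 3 of 3 pairs. Mitochondrial tRNA-Gly-TCC and the suppressor family were the other 2 of its 5 calls among 77. Mitochondrial tRNA-Phe-GAA did not pass there (log2 -1.19, SE 0.38, adjusted p = 0.0604). Without the block edgeR called 0 of the 77 (0 higher and 2 lower at unadjusted p), and with replicates 2 and 3 alone all 3 precursor families passed, with log2 changes of -1.26, -1.73 and -0.99. With replicate 1 against replicates 2 and 3 as a batch term, precursors of tRNA-Arg-TCT (-1.76) and tRNA-Ile-TAT (-1.95) passed and those of tRNA-Tyr-GTA did not (-1.64, SE 0.47, adjusted p = 0.0729).

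**Figure D3:**
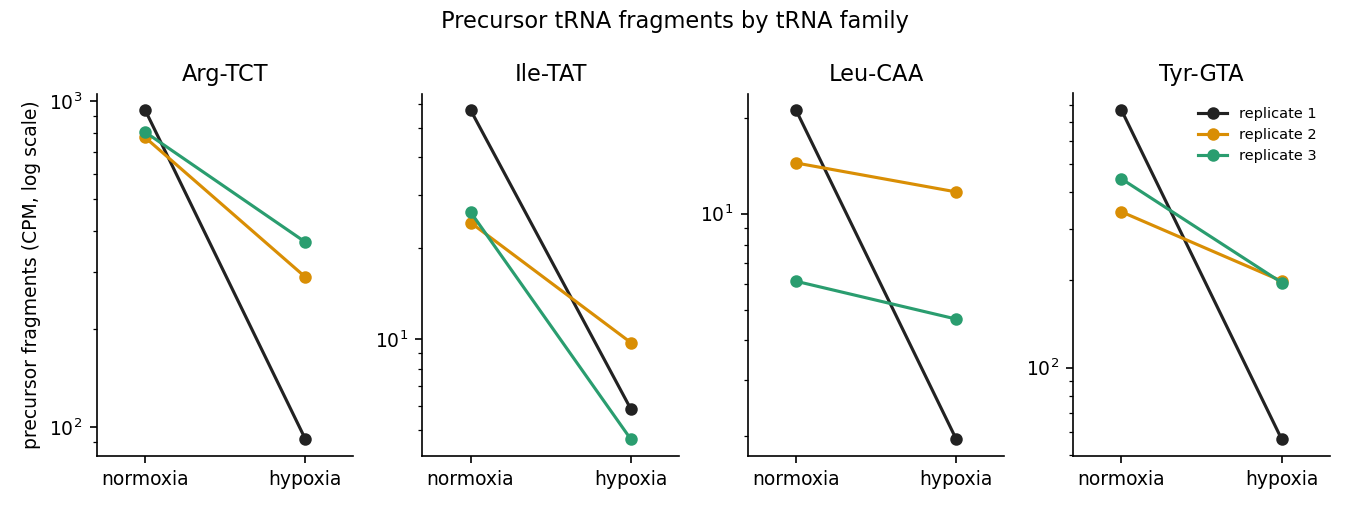
CPM of precursor tRNA fragments (vertical axes, log scale, a separate range for each panel) in normoxia and hypoxia for the 4 tRNA families with precursor sequences, each line joining a same-numbered pair of libraries. All 12 lines go down from normoxia to hypoxia, by least for tRNA-Leu-CAA in replicates 2 and 3.

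Internal fragments of tRNA-Asp, the kind of fragment named in the study's title, had 10178 ± 3883 CPM of all counts in hypoxia and 7810 ± 2919 in normoxia (exact p = 0.5), higher in 3 of 3 pairs by folds of 1.31, 1.23 and 1.36. All tRNA-Asp fragments together had 23315 ± 19611 and 18142 ± 14484 CPM (exact p = 0.5), with folds of 1.32, 1.16 and 1.3. Without hypoxia replicate 1, which leaves normoxia replicate 1 unmatched, the difference of means was -6148 CPM for all of them and 126.6 for internal ones. None of the 223 tested tRNA-Asp tsRNAs passed in edgeR, with or without the block, adjusted over all tsRNAs or adjusted over the list alone. At unadjusted p under 0.05, 3 were higher and 0 lower, and 22 and 0 with the block. Of the 223, 63 (28.3%) were higher in hypoxia in all 3 pairs and 13 (5.83%) lower, where chance gives 12.5% each, and since the study's title names a fragment of this tRNA and its design text gives the search for hypoxia-responsive tsRNAs in these libraries as the aim, the count is not taken as independent evidence of its direction. Many of these fragments overlap, so their number is not one of separate signals. DESeq2 called 0 without the block. With the block it called 2 internal fragments, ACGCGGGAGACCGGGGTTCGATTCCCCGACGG (log2 1.36, SE 0.34) and the same sequence with another G (log2 1.26, SE 0.35). In that fit 2877 of 6452 tsRNAs had no adjusted p, so the adjustment ran over fewer.

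The fragments lie on a mature tRNA-Asp-GTC of 72 nt, assembled from its overlapping fragments and of the length of all 16 annotated mouse genes of this tRNA, on 6 chromosomes, with the anticodon at positions 34 to 36. The most abundant tsRNA, the 5' fragment TCCTCGTTAGTATAGTGG (positions 1 to 18), had 7192 ± 8178 CPM in hypoxia and 5766 ± 5549 in normoxia (log2 0.32, SE 1.0). Next came internal fragments that begin right after the anticodon: ACGCGGGAGACCGGGGTTCG (positions 37 to 56) with 983.8 ± 207 against 694.8 ± 266 CPM (log2 0.50, SE 0.51), and its form longer by a base, ACGCGGGAGACCGGGGTTCGA, with 767.5 ± 417 against 432.9 ± 161 (log2 0.83, SE 0.65), both higher in 3 of 3 pairs. CGCGGGAGACCGGGGTTCG (positions 38 to 56) had a log2 change of 0.17 (SE 0.62), and CGATTCCCCGACGGG (positions 55 to 69), the internal fragment with the smallest p, had 32.8 ± 6.82 against 8.73 ± 2.95 CPM (log2 1.90, SE 0.67). As a family, tRNA-Asp-GTC had a log2 change of 0.30 (SE 0.42, adjusted p = 0.996) in edgeR and 0.30 (SE 0.13, adjusted p = 0.226) with the block, higher in 3 of 3 pairs. It passed in the blocked fits with DESeq2 (log2 0.47, adjusted p = 0.0117) and with DESeq2 size factors in edgeR (0.47, adjusted p = 0.0482), within a range of 0.0117 to 0.999 over all settings, and without hypoxia replicate 1 its log2 change was -0.08. Relative to the family median the unblocked change was 0.37 with either scaling.

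**Figure D4:**
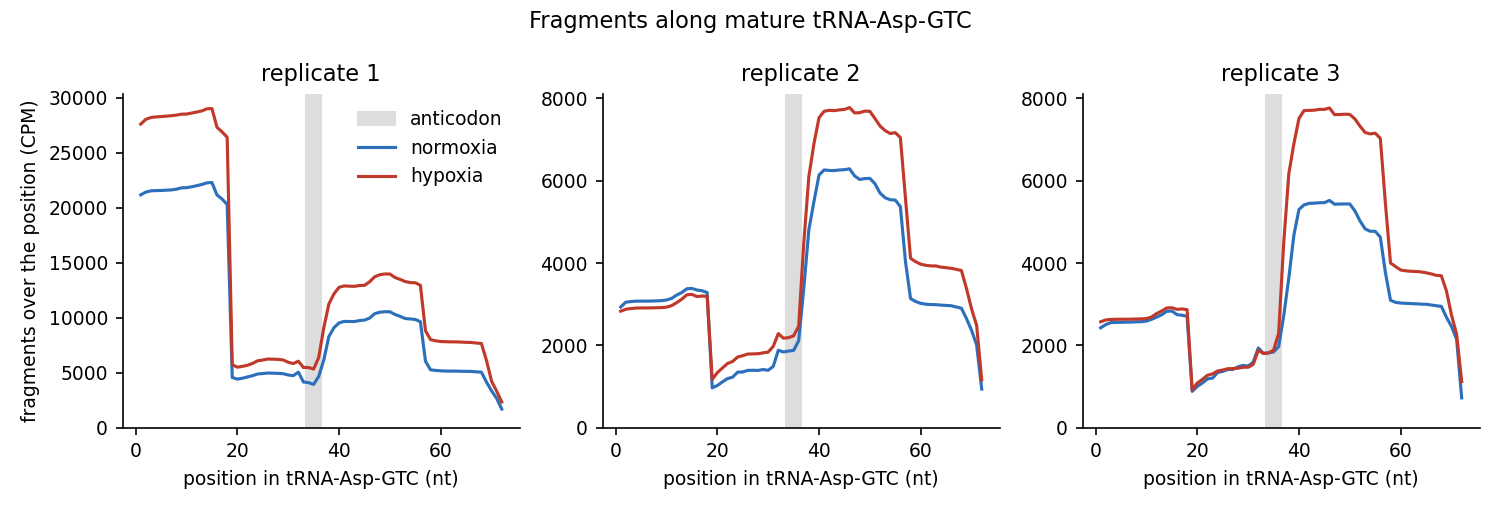
CPM of fragments covering each position of mature tRNA-Asp-GTC (horizontal axis, nt from the 5' end; vertical axes with a separate range for replicate 1) in the same-numbered libraries of hypoxia (red) and normoxia (blue), with the anticodon at positions 34 to 36 shaded. The hypoxia line lies above the normoxia line after the anticodon in each pair, and the 5' part is higher than the part after the anticodon only in replicate 1.

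Among the lists of tsRNAs fixed beforehand, 16 of 33 passed a competitive test with a preset correlation (camera), and 0 passed with an estimated correlation. The lists higher in hypoxia were tRNA-Asp (adjusted p = 0.00379), tRNA-Glu (0.034), tRNA-Pro (0.0362), tRNA-Val (0.00525), 3' ends without CCA (2.08e-05), the tRNAs Asp, Glu, Gly and Tyr as a group of sources of YBX1-binding fragments (0.0436), and the DNMT2 substrates Asp-GTC, Gly-GCC and Val-AAC (0.0181), DNMT2 being a methyltransferase of the tRNA anticodon loop. Their median log2 changes were 0.34, 0.15, 0.26, 0.25, 0.60, 0.13 and 0.21. The list of 3' ends without CCA holds fragments that end on the last encoded base. Those that end in C or CC of the tail are in the internal list. The lists lower in hypoxia were precursor tRNA (adjusted p = 4.15e-23, median log2 -1.54), tRNA-Tyr (0.00956), tRNA-Lys (0.0161), CCA ends (0.0228), mitochondrial tRNAs (0.034), tRNA-Met (0.034), and the tRNAs Ala, iMet and Phe (0.0436 each). With the estimated correlation the adjusted p of the 33 lists lay between 0.293 and 0.886, and with fry's directional test between 0.426 and 0.961. With the block 15 passed with the preset correlation, among them tRNA-Ile and neither tRNA-Met nor iMet, and 0 passed with an estimated correlation (adjusted p from 0.333) or with fry's directional test (from 0.37). In fry's mixed test, for changes in either direction, 0 passed without the block (from 0.291) and 1 with it, tRNA-Tyr (adjusted p = 0.0294). The lists for the tRNAs Arg, Asn, Cys, Gln, Gly, His, Ile, Leu, SeC, Ser, Thr and Trp and the suppressor tRNAs, the 5' ends, the internal fragments, the sources of abundant long 5' fragments and the sources of sex-hormone-dependent long fragments did not pass without the block. For the last of these lists the sign of camera (lower) differed from that of fry and of the median (0.01).

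No list had a member that passed without the block, adjusted over all tsRNAs or adjusted over the list alone. With the block and adjusted over the list alone, 11 of the 21 tested precursor fragments fell and 0 rose, and 15 of 852 mitochondrial tsRNAs rose and 7 fell. Of the 155 tested 3' ends without CCA 7 rose and 1 fell, and 2 fell and 0 rose among each of 91 tRNA-Ile, 68 tRNA-Tyr and 877 5' end tsRNAs. Adjusted over all tsRNAs with the block, the mitochondrial list held 5 that rose and 3 that fell, and the precursor list 1 that fell. Of the same 10 calls, the internal fragments held 4 that rose and 2 that fell, the 3' ends without CCA 1 that rose, and the 5' ends 2 that fell. The lists of tRNA-Ile, of tRNA-Tyr and of the tRNAs Asp, Glu, Gly and Tyr as a group held 1 each that fell. For tRNA-Tyr and for the group it was the precursor fragment of tRNA-Tyr-GTA. Of the precursor list 71.4% of members were lower in all 3 pairs and 0 higher. Fragments of the same tRNA overlap, so none of these counts of members is one of separate signals.

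The shares of the 4 mature fragment classes differed between hypoxia and normoxia by less than the larger SD of the groups. The 5' ends made up 47.6 ± 9.55% in hypoxia and 49.5 ± 13% in normoxia (two-sided exact permutation p = 0.7), internal fragments 45.8 ± 8.54% and 43.7 ± 12.2% (exact p = 0.6), CCA ends 4.96 ± 1.07% and 5.66 ± 0.633% (exact p = 0.5), and 3' ends without CCA 1.60 ± 2.10% and 1.05 ± 1.37% (exact p = 0.5). Within the pairs CCA ends were lower in hypoxia in 3 of 3, by -1.21, -0.515 and -0.392 percentage points, and 3' ends without CCA were higher in 3 of 3, by 1.39, 0.118 and 0.130 (exact p = 0.25 over 3 pairs for each, the smallest that 3 pairs allow). Over replicates 2 and 3 the mean difference was -3.79 percentage points for 5' ends and 4.18 for internal fragments. Fragments that end in the C or CC of the tail are counted as internal, not as 3' ends without CCA. In a check that was not planned they made up 5.51 ± 0.298% of internal counts in hypoxia and 4.58 ± 0.152% in normoxia. The groups did not overlap (exact p = 0.1), and hypoxia was higher in 3 of 3 pairs.

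**Figure D5:**
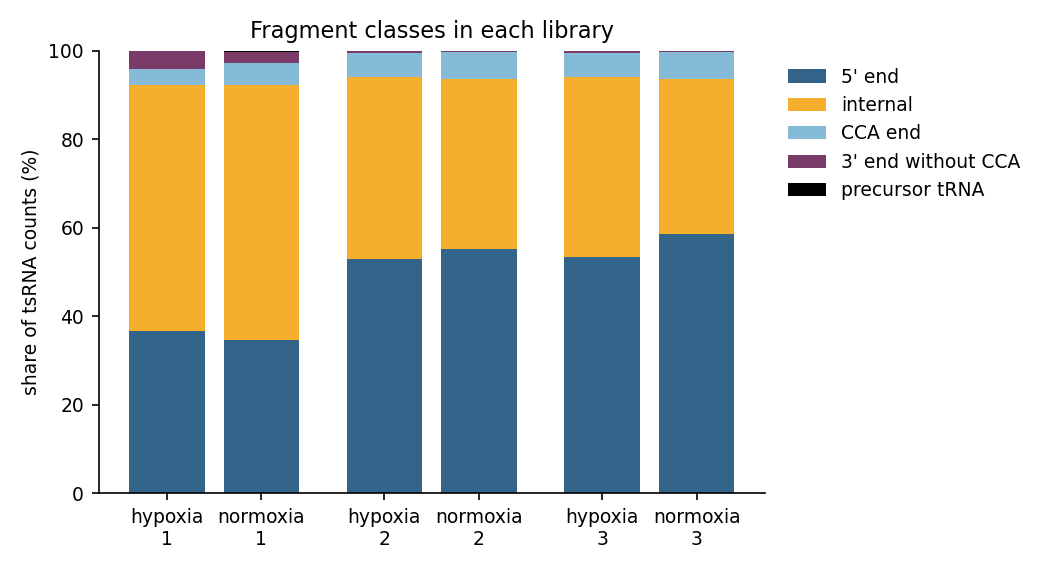
Share of tsRNA counts (vertical axis, percent) in each fragment class for each of the 6 libraries. The libraries numbered 1 hold 36.6% and 34.6% in 5' ends, and the other 4 hold 53.0% to 58.6%.

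By length, fragments of 24 nt or shorter made up 70.9 ± 3.87% in hypoxia and 71.8 ± 5.33% in normoxia (exact p = 0.8), those of 25 to 29 nt 9.58 ± 1.77% and 9.76 ± 2.28% (exact p = 0.9), those of 30 to 40 nt, the size range of fragments cleaved in the anticodon loop, 17.5 ± 1.47% and 15.8 ± 2.69% (exact p = 0.4), and longer ones 2.11 ± 0.867% and 2.58 ± 0.588% (exact p = 0.5). In all 3 pairs the 30 to 40 nt class was higher in hypoxia and the longest class lower (exact p = 0.25 for each). The mean length was 21.9 ± 0.784 nt in hypoxia and 21.7 ± 1.02 nt in normoxia (exact p = 0.7). Mitochondrial tRNAs supplied 9.10 ± 5.33% of counts in hypoxia and 9.44 ± 4.28% in normoxia (exact p = 0.8), with pair differences of 0.892, -0.631 and -1.29 percentage points. Each of these length and mitochondrial differences was smaller than the larger SD of the groups. Over replicates 2 and 3 alone the mean mitochondrial difference was -0.958 percentage points and that of the 30 to 40 nt class 2.28.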

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

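The settings that combine the replicate block with another choice, leave out a pair, use a batch term or replicates 2 and 3 alone, or set precursors apart were chosen only after the results were seen, as were all settings for totals, tRNA-Asp sums, precursor sums and mitochondrial tRNA-Val ends. With the group alone, 0 tsRNAs and 0 tRNA-Asp tsRNAs passed in edgeR under each scaling and filter and without each replicate in turn, in DESeq2 and in limma voom (at unadjusted p under 0.05, 34 higher and 50 lower in DESeq2, 56 and 53 in limma voom, and 13 to 244 higher and 8 to 229 lower over the edgeR settings). The number of tsRNAs past the threshold, the same at 2-fold or more, was 10 with the replicate block, 10 with library size and the block, 11 with upper-quartile factors and the block, 12 with DESeq2 size factors and the block, 28 with DESeq2 and the block, 9 with limma voom and the block, 5 with the batch term, 1 with replicates 2 and 3 alone, 26 with the block without pair 1, 0 without pair 2 and 21 without pair 3. Of the 10 blocked calls these shared 10, 10, 10, 10, 10, 6, 5, 1, 7, 0 and 10, and their adjusted p over all settings ran from 1.62e-08 to 1.0. In DESeq2 with the block 2877 of 6452 tsRNAs and 9 of 73 families had no adjusted p. Its 28 calls therefore rest on an adjustment over fewer tsRNAs than the others. The dispersion is 0.213 with the block and 0.706 without it, so the block leaves less residual spread to test against.

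Families past the threshold numbered 1 with library size only, 2 with DESeq2, 3 with the block, 3 with library size or upper-quartile factors and the block, 4 with DESeq2 size factors and the block, 5 with DESeq2 and the block, 5 with limma voom and the block, 4 with the batch term, 8 with replicates 2 and 3 alone, 13 with the block without pair 1, 0 without pair 2 and 2 without pair 3 (mitochondrial tRNAs Phe-GAA and Gly-TCC), and 0 to 1 without each replicate in turn. With precursors apart they numbered 5 with the block, 3 with the batch term (the suppressor family and precursors of tRNA-Ile-TAT and tRNA-Arg-TCT) and 9 with replicates 2 and 3 alone. The suppressor family was the call with library size only and without normoxia replicate 1. The 4 calls of DESeq2 with the block that rose were the tRNAs Asp-GTC, Leu-AAG and Leu-TAG and mitochondrial tRNA-Val-TAC, and the batch term added mitochondrial tRNA-Asp-GTC to the 3 blocked calls, to which limma voom with the block added mitochondrial tRNAs Ser-GCT and Ile-GAT. tRNA-Asp tsRNAs past the threshold numbered 2 with DESeq2 and the block and 1 with the block without pair 1 (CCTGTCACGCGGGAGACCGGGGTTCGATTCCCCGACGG). The log2 change of family Asp-GTC was 0.47 in both settings where it passed and -0.084 to 0.67 without each replicate in turn. Lists past the threshold numbered 0 with an estimated correlation, 0 with fry's directional test, and 0 with either and the block. With the block fry's mixed test passed tRNA-Tyr (adjusted p = 0.0294), a list that includes precursor fragments.

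Of 618 log2 changes of 25 named tsRNAs over the settings, 516 kept their direction and their side of the threshold, 80 passed it in the same direction and 22 reversed. Reversals without a replicate gave ranges of -1.06 to 0.14 for GGGGATGTAGCTCAG, -1.16 to 0.025 for GGGGATGTAGCTCAGTG, -0.74 to 0.27 for GGGGATGTAGCTCAGTGG, -0.49 to 0.51 for GGGGATGTAGCTCAGTGGT, -0.034 to 0.91 for AGGATTCGGCGCTCTC, -1.18 to 1.46 for TCCTCGTTAGTATAGTGG and -0.23 to 0.58 for CGCGGGAGACCGGGGTTCG. With the block without pair 3 the first was 0.059, the third 0.062, AGGATTCGGCGCTCTC -0.15 and CGCGGGAGACCGGGGTTCG -0.11. GGGGATGTAGCTCAGTGGT was 0.028 without a filter, 0.039 with replicates 2 and 3 alone and 0.037 with the block without pair 1, and TCCTCGTTAGTATAGTGG was -0.052 and -0.044 in the last 2 of these settings. Shares that reversed, in percentage points, were 5' ends (0.0617 without the 10 most abundant tsRNAs, -9.30 to 3.67 without each replicate in turn), 3' ends without CCA (-0.666 to 1.34), internal fragments (-2.83 to 9.11), 24 nt or shorter (-3.95 to 1.25), 25 to 29 nt (0.104 with replicates 2 and 3 alone, -1.21 to 1.12), mitochondrial tRNAs (-3.42 to 2.12) and the mean length (-0.280 to 0.748 nt). Without each replicate in turn the difference of total counts ran from -327770 to 746028, that of tsRNAs with at least 10 counts from -167.2 to 1414, that of tRNA-Asp CPM from -6148 to 13527 and that of mitochondrial tRNA-Val ends at positions 65 to 67 from -32.3 to 16692 CPM. Leaving out 1 library leaves the other library of its pair unmatched, and apart from this the cause was not tested for any of the reversals. Precursor CPM stayed lower in hypoxia (-1121 to -677.3) and the CCA share of mitochondrial tRNA-Val too (-22.2 to -15.5 percentage points) in all their settings. Depth limits tsRNAs most in the shallowest library, with 330787 counts.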

Other observations

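The tests of start and end positions, of the 3 patterns below and of swaps within pairs were chosen only after the results were seen, and the counts over 10 splits were planned. Within tRNA-Asp-GTC, fragments that start at position 37, the first base after the anticodon, had 3178 ± 874 CPM of all counts in hypoxia and 1866 ± 772 in normoxia (SD, n = 3 per group; two-sided exact permutation p = 0.2), with pair folds of 1.54, 1.54 and 2.29. The difference of 1312 CPM ran from 809.6 to 1736 without each replicate in turn. Fragments with this start made up 33.6 ± 3.08% of internal tRNA-Asp-GTC counts in hypoxia (30.4%, 33.9% and 36.6%) and 24.7 ± 2.88% in normoxia (25.5%, 27.0% and 21.5%), without overlap (exact p = 0.1, the smallest possible). Those that start at position 38 had 1836 ± 310 and 1504 ± 620 CPM (exact p = 0.4), with pair folds of 1.02, 1.15 and 1.81, and those that start at positions 35 and 36 were also higher in 3 of 3 pairs, by 2.13, 1.22 and 1.60 and by 1.43, 1.24 and 2.45, so that higher CPM was not particular to position 37. Both tRNA-Asp fragments that DESeq2 called with the block start at position 37 and end at positions 68 and 69.

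Fewer 3' ends of mitochondrial tRNA-Val carried a full CCA tail in the hypoxia libraries. Of its fragments that end in CC or CCA, 39.7 ± 0.851% carried the full CCA in hypoxia and 58.5 ± 7.35% in normoxia, without overlap (exact p = 0.1). In the other mitochondrial tRNAs the share was 59.8 ± 8.59% and 72.4 ± 5.68% (exact p = 0.2), lower in 3 of 3 pairs on 113 to 876 counts per library, and in nuclear tRNAs 84.5 ± 12.4% and 85.5 ± 11.7% (exact p = 0.5), also lower in 3 of 3 pairs, by -1.82, -1.04 and -0.156 percentage points. As a share of all 3' ends, the CCA ends of nuclear tRNAs differed by -8.02, -2.13 and -2.70 points and those of mitochondrial tRNA-Val by -29.8, -15.4 and -15.5. The data hold no sequence under 15 nt, so late-starting fragments without a tail are missed in this share. Among mitochondrial tRNA-Val fragments starting at or before position 55, which are long enough for each end, the differences were -30.2, -20.9 and -16.2 points.

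The lower CCA share of mitochondrial tRNA-Val was weighed against 3 explanations. A loss of the last base in all tRNAs of the hypoxia libraries as the whole cause is argued against by nuclear tRNAs, whose lowest pair difference was -1.82 percentage points, while that of mitochondrial tRNA-Val was at most -14.8, and a small loss in all tRNAs stays open. A single start position is argued against as well, since fragments starting at 55, 56 and 57 were each lower in all pairs, the smallest difference being -11.1 points. The other mitochondrial tRNAs were lower in every pair, with -4.78 points as the smallest difference, so the change may be shared by mitochondrial tRNAs. Whether hypoxia or a handling difference between the groups' cultures is behind it stays open, as neither was tested apart.

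The lower precursor fragments were weighed in the same way. A single tRNA or a few sequences as the cause is argued against, since with each tRNA or the 10 most abundant sequences left out every pair stayed lower, the highest log2 ratio being -0.80. Fewer fragments of the tRNA as a whole is argued against for tRNA-Arg-TCT and tRNA-Tyr-GTA, whose mature fragments had their lowest pair at 0.17 and -0.25, against -1.12 and -0.79 for the pair of precursors that fell least, while it stays open for tRNA-Ile-TAT (lowest mature pair -0.78, with 3 to 54 precursor counts per library) and tRNA-Leu-CAA (-0.071, with 1 to 32). A bias against scarce sequences is argued against by 1000 draws of mature internal fragments matched in abundance and length, where the pair that fell least reached at lowest -0.11 against -1.16 for precursors. Less unspliced tRNA-Arg-TCT and tRNA-Tyr-GTA in hypoxia may be behind their part of the pattern, as a hypothesis found and tested on the same data, and a difference in RNA recovery between the groups' cultures was not tested.

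Replicate 1 of both groups stood apart. Fewer counts drawn from a pool like that of the others is argued against, since at 330787 counts the other 4 libraries held at most 11130 distinct tsRNAs, against 18948 in normoxia 1 and 19309 in hypoxia 1. A few abundant tsRNAs are argued against for the mitochondrial shares alone, which lay at least 5.54 percentage points apart without the 10 most abundant. For the 5' end shares a few abundant tsRNAs stay open, since the gap was not tested without them. The most abundant tsRNA, a 5' end shared by the tRNA-Ala families, differed in the same direction. It had 5031 scaled CPM in hypoxia 1 and 4289 in normoxia 1, against 73031 to 135041 in the other 4 libraries. Hypoxia 1 and normoxia 1 deviated from their group means together (r = 0.81 across tsRNAs, which are not independent), but this restates the pattern. Separate preparation or growth of replicate 1 stays open, since the labels give no batch or date, and no biological explanation was tested.

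For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Real and highest other counts were 0 and 0 for tsRNAs, for tsRNAs at 2-fold or more, for tRNA-Asp tsRNAs and for families, so that all 10 splits gave as many in each. For lists with the preset correlation they were 16 and 16, in 2 of the 10 splits. The other split with 16 joined hypoxia 1 and 2 with normoxia 1, and the 4 splits that kept both libraries numbered 1 together gave 13 to 16 lists, which points to the structure of the replicates. Of the splits that part all 3 pairs, the 3 others gave 4, 5 and 7 lists against 16 for the real one, all without the block, and lists were tested with the block on the real split alone (15 lists). Swaps within pairs make 4 splits, also too few: with the block, real and highest other counts were 10 and 0 for tsRNAs, 3 and 0 for families, and 5 and 0 for families with precursors apart, each reached by 1 of the 4.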
